A study of Mus musculus with 12 samples.

How the data were processed

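Gene expression was measured in B cells from mouse spleens in 12 libraries, 3 for each of 4 treatments: none, a class B CpG-ODN, IM156, and both. Per the sample labels, C57BL/6 wild-type mice (lupus-prone in the series description) aged 7 weeks received 50 µg of ODN into the peritoneum on days 1 and 3, and IM156 at 30 mg/kg by the same route on days 0 and 2; spleens were taken on day 4. RNA was isolated with TRIzol, and libraries were made with the Lexogen QuantSeq 3' mRNA kit, which yields reads from the 3' end of each transcript. The labels give no vehicle for the untreated controls, no sex of the mice, no number of animals behind each library and no batch. The p-values therefore measure the spread between these samples, pooled over the 4 treatments, whichever number of animals they stand for.

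The deposited table holds raw read counts per gene for each library (unit: counts) in 23282 rows named by gene symbol. Per the labels, the processing tools were Bowtie2, bedtools and edgeR with the GRCm38 (mm10) genome; their versions, the gene annotation and the strand rule of the counting are not stated. The same deposited table gives the authors' fold changes, a linear ratio between group means, and the authors' p-values (a p_value column for each comparison), with no statement of the test or of an adjustment. It also holds 12 columns of normalized values and 4 of group averages, which were not used. The counts were checked to be whole numbers whose column totals differ between libraries. Of the rows, 5883 had no count in any library; 35 symbols stood on 79 rows, which were kept apart. The table has no row for immunoglobulin constant regions such as Ighm and Ighg2c, and none for genes encoded by mitochondrial DNA, so that 1 of the 35 gene lists below could not be tested. Named genes were placed on GRCm38 with the GENCODE annotation, in which 386 of 389 symbols were found. Some overlap a protein-coding gene on the opposite strand, among those named Ndufb5 (Mrpl47), Junb (Prdx2), Dusp1 (Ergic1), Psph (Cct6a), Rpl32 (Cand2) and Sla (Tg). Without a stated strand rule, reads in the shared stretch cannot be told apart. Psmb9 and Tap1 overlap only at the 5' ends of both, away from the 3' ends that these libraries read.

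Total counts per library lay between 9650775 and 11532525, and the median count of a tested gene in a library was 258. Between replicates of a group, squared differences were 5.143 to 67.84 times those of counting error alone (chi-square per degree of freedom over genes with at least 20 counts). The ribosomal RNA row Rn45s was included and weighs heavily in the 2 highest values, those of pairs with ODN replicate 2. It had 167940 counts there, against 827396 and 920348 in ODN replicates 1 and 3, a pair at 22.31. The spread between libraries, not depth, therefore limits the precision of well-counted genes. Reads carry no molecular identifiers; intervals and floors from counts cover counting error only. The floor for a count of 0 was 3 counts, and confidence levels were 95%.

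Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings (11857 genes), and libraries were scaled with TMM factors. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which leaves 8 residual degrees of freedom. It takes 1 spread per gene over all groups. Replicates of ODN differed most, with chi-square per degree of freedom of 22.31 for their closest pair, against at most 18.63 in the other groups. Comparisons with the ODN group may therefore get p-values too small, and those without it p-values too large. The comparisons were ODN against control, IM156 against control, ODN+IM156 against each of ODN, control and IM156, and the interaction, the effect of IM156 with ODN minus its effect without ODN. Tests were two-sided, and p-values were adjusted with Benjamini-Hochberg over all genes tested within a comparison; a gene was called at an adjusted p below 0.05. Levels are in counts-per-million units (CPM) of the scaled library, as mean ± SD of 3 libraries, and fold changes are log2 values with the standard error of the fit.

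Each gene list with at least 5 tested members (34 of 35) was tested with camera (limma 3.58.1), which compares the list with all other genes, at the preset correlation of 0.01 between genes, adjusted over the 34 lists. The lists cover metabolism, stress and interferon responses, B-cell states, the cell cycle, ribosomal proteins and markers of other cell types. Camera with a correlation estimated for each list and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Calls of members are given over all genes tested and adjusted over the list alone. The gene lists, the comparisons, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, in each comparison, up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between the libraries of both groups. It also names up to 4 members of each described list by smallest p, the 5 genes of smallest p where fewer than 10 are called, and genes fixed by name, among them Tlr9, Prdm1, Mki67, Cd86, Cd69, Isg15, Ighm, Ighg2c, Ddit3 and Asns. Predicted genes and clone names were counted, not named. Genes outside this rule are marked as chosen after their values were seen.

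The slope of the ODN response with IM156 on the response without it was taken through the origin across the genes called for ODN against control. Since genes picked by 1 comparison move less in another by chance, the slope was also computed in 20 sets of counts simulated with the same response in both. The simulated effects were used as fitted and also shrunk to 0.8 of their size, the value at which as many genes were called as in the data; the shrinkage was added after a first simulation called too many. The pipeline was tested on simulated data with genes changed by known folds in 3 libraries against 3: edgeR recovered 52.2% of 1.5-fold, 74.6% of 2-fold and 90.9% of 3-fold changes, with 10 false calls among 155. DESeq2 1.42.0 recovered 56.7%, 79.1% and 92.4%, with 15 false calls among 167.

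Alternatives set in advance were RLE size factors, DESeq2, no filter and a stricter filter of 10 CPM in 3 libraries, only the libraries of the groups compared, the replicate number as a block, a robust fit, an added 2-fold minimum, and leaving out each library. Added after the data were seen were library totals without further scaling, leaving out the ribosomal RNA row, a correction for transcript length, and the block with that correction. The slope over all genes of at least 10 CPM was also added then. Libraries with the same replicate number were not treated as pairs. No library was left out of the comparisons as given.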

Results

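Transcript levels were measured in splenic B cells from injected or untreated mice in 4 groups of 3 libraries: control (no treatment), ODN, IM156 and ODN+IM156. The sample labels give the mice as wild-type C57BL/6, whereas the series description calls them lupus-prone, and the counts do not settle which holds. ODN stands for a class B CpG-ODN, a synthetic DNA with unmethylated CpG motifs that activates the endosomal receptor TLR9, and IM156 is described by the series as an inhibitor of oxidative phosphorylation. Levels below are in counts-per-million units (CPM), mean ± SD of 3 libraries per group (n = 3). Total counts per library were 9891730 to 10993791 in control, 10372508 to 11532525 in ODN, 10019443 to 11285692 in IM156 and 9650775 to 11103365 in ODN+IM156. The ribosomal RNA row Rn45s held 8.36 ± 1.14% of the counts in control, 5.95 ± 3.9% in ODN, 6 ± 1.75% in IM156 and 7.2 ± 1.75% in ODN+IM156. Within the ODN group, replicate 2 stood apart with 1.46% (95% Wilson interval 1.45% to 1.46%). The 27 measured B-cell identity genes, such as Cd79b and Ms4a1, summed to 16310 ± 608 CPM in control, 16970 ± 156 in ODN, 16120 ± 161 in IM156 and 16290 ± 455 in ODN+IM156. ODN replicate 3 held 1 count of Xist, the RNA of the inactive X chromosome, against 923.3 to 1319 CPM in the other 11 libraries. Xist, a gene chosen after its values were seen, overlaps its antisense gene Tsix. The transcript of the ODN receptor itself, Tlr9, had 68 counts over all libraries and was not tested.

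ODN against control compares B cells of mice injected with the TLR9 ligand alone with those of untreated mice. No vehicle is given for the controls, so effects of the ligand and of the injections cannot be told apart. Most genes of mitosis, S phase and the ribosome rose, as did some interferon-induced and respiratory chain genes, while haemoglobin transcripts and some immediate-early and follicular B-cell genes fell. Of 34 lists, 20 passed camera at the preset correlation and 2 with an estimated correlation, those of platelets and NK cells (adjusted p = 0.0419 each). Only 8 of the 17 listed NK-cell genes had enough counts to be tested. Among called genes with a mean of at least 10 CPM and no overlap between the libraries of both groups, Iigp1 and Ly6c2 rose most. Iigp1, an interferon-inducible GTPase, went from 1.59 ± 1.22 to 14.3 ± 5.77 CPM (log2 fold change 3.16, SE 0.432, adjusted p = 0.000134). Ly6c2, a surface antigen of monocytes and some lymphocytes, went from 11.3 ± 0.675 to 92.3 ± 51.1 CPM (3.02, SE 0.263, adjusted p = 1.2e-06). In GRCm38, Iigp1 lies on chromosome 18 at 60376027 to 60392634 and Ly6c2 on chromosome 15 at 75108158 to 75111970. The next 6 rises by the same rule were in Esco2, Neurl1b, Cdc6, Spag5, Cdk1 and Tcf19, with log2 fold changes from 2.35 for Tcf19 to 2.69 for Esco2. Of these, Esco2, Cdc6, Spag5 and Cdk1 act in DNA replication or chromosome segregation. In all, edgeR called 1255 of 11857 genes, 870 higher and 385 lower, of which 351 changed at least 2-fold. DESeq2 called 1469, and 2987 genes had an unadjusted p below 0.05. The share of called genes that were higher, 69.3%, depends on the scaling: with library totals alone it was 49.1% (695 higher, 720 lower). The count was 763 without ODN replicate 1, 811 without control replicate 3 and 1874 without ODN replicate 3. A fit of only the ODN and control libraries called 598 genes (490 higher, 108 lower).

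Genes of the cell cycle had higher levels under ODN. Of 40 measured genes of mitosis and G2/M phase, 39 rose over all genes tested and 40 adjusted over the list alone, with a median log2 fold change of 1.85. Top2a, a topoisomerase of dividing cells, went from 99.5 ± 27.2 to 486 ± 331 CPM and the proliferation marker Mki67 from 48.1 ± 19.2 to 196 ± 136. Cdk1, the kinase of mitotic entry, went from 14.7 ± 4.99 to 75.7 ± 41.3 (log2 fold change 2.36, SE 0.308, adjusted p = 8.5e-05). Of 38 genes of DNA replication and S phase, 28 rose (36 adjusted over the list alone, median 0.91), among them Pole, from 8.22 ± 2.34 to 22.4 ± 6.32 CPM, and Mcm6, from 41.2 ± 4.24 to 79.4 ± 24.2. The ODN libraries differed widely: the median of the mitosis genes against the control mean was 2.67 in replicate 1, 1.56 in replicate 2 and 0.82 in replicate 3. Without ODN replicate 1, 34 of the mitosis genes and 15 of the S-phase genes were called; without control replicate 2, 17 of the S-phase genes were. Camera with the preset correlation called both lists; adjusted p = 0.155 for mitosis and 0.238 for S phase with an estimated correlation.

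All 60 ribosomal protein genes had positive fold changes and 59 rose, both over all genes tested and adjusted over the list alone, with a median of 0.53. Rpl32 went from 2630 ± 195 to 4630 ± 364 CPM and Rps12 from 447 ± 24.5 to 782 ± 83.7 (0.81, SE 0.0918, adjusted p = 2.27e-05). Reads of processed pseudogenes of this family cannot be separated from those of the parent genes. The list had adjusted p = 0.0661 with an estimated correlation. Of 42 OXPHOS complexes II to V subunits, 24 rose (32 adjusted over the list alone, median 0.39, adjusted p = 0.192 with an estimated correlation). The count was 14 without control replicate 3. Uqcrh of complex III went from 438 ± 41 to 673 ± 67.1 CPM and Sdhd of complex II from 52.5 ± 3.2 to 81.3 ± 10.8. Of 36 OXPHOS complex I subunits, 12 rose (16 adjusted over the list alone, median 0.24, adjusted p = 0.32 with an estimated correlation), with Ndufb5 going from 135 ± 8.49 to 196 ± 26.7 CPM. That count of 12 was 3 without control replicate 3, 5 without ODN replicate 1, 4 without ODN replicate 2, and 5 after a correction for transcript length or with library totals alone. In glycolysis 5 of 18 genes rose (6 adjusted over the list alone, median 0.22, adjusted p = 0.277 with an estimated correlation). Among them Gpi1 went from 121 ± 14.4 to 191 ± 16 CPM and Ldha from 112 ± 0.0655 to 153 ± 17.1. For glycolysis the count was 2 without control replicate 2 or ODN replicate 1 and 3 without control replicate 3 or ODN replicate 2. Mdh1 and Idh2 were the 2 called genes of 18 in the TCA cycle (median 0.15, adjusted p = 0.407 with an estimated correlation), and neither call held without ODN replicate 1, ODN replicate 2, control replicate 1 or control replicate 3. Genes of the endoplasmic reticulum rose in 7 of 37 cases (7 adjusted over the list alone, median 0.16, adjusted p = 0.403 with an estimated correlation), and 4 did without ODN replicate 1. The translocon gene Sec61g went from 145 ± 7.87 to 224 ± 37.5 CPM and the signal sequence receptor gene Ssr4 from 130 ± 16.2 to 205 ± 25.9. The nucleolar and ribosome biogenesis genes linked to mTORC1 and MYC passed camera in the opposite direction (median -0.12, adjusted p = 0.483 with an estimated correlation). Single members were 1 of 32 higher (Npm1, from 549 ± 23.1 to 864 ± 109 CPM) and 1 lower (Rcl1, from 67.2 ± 11.7 to 45.3 ± 2.41). The list did not pass without control replicate 1, ODN replicate 1 or ODN replicate 2.

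Of 27 interferon-gamma inducible GTPases, guanylate-binding proteins and partner genes, 12 rose (17 adjusted over the list alone, with 1 lower, median 0.47, adjusted p = 0.112 with an estimated correlation). Psmb9, a subunit of the immunoproteasome, went from 164 ± 16.2 to 302 ± 24.1 CPM (0.88, SE 0.0902, adjusted p = 7.8e-06) and Gbp2 from 25.9 ± 1.07 to 53.5 ± 8.24. Psmb9 overlaps Tap1 on the opposite strand only at the 5' ends of both genes, away from the 3' ends that these libraries read. Tgtp1 went from 12.4 ± 1.87 to 35.5 ± 11, although its near-identical neighbour Tgtp2 makes the source of its reads uncertain. Of 48 type I interferon-stimulated genes, 10 rose (15 adjusted over the list alone, median 0.12, adjusted p = 0.277 with an estimated correlation). They included Ly6a, from 343 ± 14 to 794 ± 137 CPM, Ifi44, from 2.01 ± 0.281 to 8.09 ± 2.43, and the ubiquitin-like modifier Isg15, from 19.9 ± 5.44 to 35.8 ± 3.7. The NF-kB and TLR target genes did not pass as a group: 7 of 37 members rose (8 adjusted over the list alone, with 1 lower), and camera gave an adjusted p of 0.0573 at the preset correlation. The called members included Cd83, from 226 ± 23.4 to 356 ± 64.6 CPM, and Bcl2a1d, a survival gene with near-identical copies, from 46.2 ± 3.79 to 82.4 ± 10.3.

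Markers of B-cell states moved apart. In the list of age-associated B cells, 8 of 18 genes rose and 1 fell (10 and 1 adjusted over the list alone, median 0.79, adjusted p = 0.112 with an estimated correlation). Without ODN replicate 1, 5 rose. Itgax, which encodes CD11c, went from 4.61 ± 0.688 to 10.8 ± 0.884 CPM and the Fc receptor-like gene Fcrl5 from 32.5 ± 4.68 to 55.2 ± 6.22. Itgax also stands on the dendritic cell list, which summed to 1922 ± 64.1 CPM in control and 2243 ± 44 in ODN, so its cell of origin is open. Ahnak, a large scaffold protein, went down from 65.1 ± 9.76 to 25.4 ± 4.66 (-1.35, SE 0.146, adjusted p = 1.23e-05). Of 16 follicular B-cell genes, 5 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.112 with an estimated correlation). Without control replicate 2, ODN replicate 1 or ODN replicate 2, 3 fell. Fcer2a, which encodes CD23, went from 341 ± 62.7 to 226 ± 12.2 CPM and Cd55 from 248 ± 23.5 to 176 ± 23.6. Of 20 germinal centre B-cell genes, 4 fell (5 adjusted over the list alone, median -0.39, adjusted p = 0.288 with an estimated correlation). Lmo2 went from 260 ± 22.7 to 205 ± 14 CPM and S1pr2 from 7.94 ± 5.43 to 2.36 ± 1.12. The number of calls was 1 without control replicate 3 or ODN replicate 2 and 0 without ODN replicate 1. Plac8, a gene of marginal zone B cells, went from 668 ± 20.7 to 1460 ± 296 CPM, while Myof and S1pr3 of the same list of 20 fell (2 higher, 2 lower, camera adjusted p = 0.703). Myof was not called without control replicate 2, and S1pr3 without control replicate 1, control replicate 2, ODN replicate 1 or ODN replicate 2. Of 21 immediate-early genes, 6 fell and 2 rose (6 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.25 with an estimated correlation). Klf4 went from 146 ± 25.8 to 66.9 ± 12.7 CPM, Junb from 313 ± 31.1 to 197 ± 12.6 and Dusp1 from 84.7 ± 6.92 to 48 ± 12.5. Immediate-early genes also respond to the handling of cells. The activation marker Cd69 fell from 75.2 ± 14.2 to 49.4 ± 2.79 CPM. Cd86 (24.1 ± 2.07 and 27 ± 0.606 CPM), Prdm1 (5.71 ± 2.18 and 5.18 ± 2.25), Ddit3 (62.6 ± 7.99 and 60.3 ± 6.15) and Asns (1.23 ± 0.632 and 1.42 ± 0.343) did not pass the test.

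Transcripts of other cell types moved in both directions with ODN. Haemoglobin genes made up the largest falls by that rule: Hba-a1 went from 346 ± 46.9 to 80.9 ± 38 CPM and Hbb-b1 from 134 ± 16.7 to 29.3 ± 13.1 (-2.18, SE 0.474, adjusted p = 0.00489). Hbb-bs, Hbb-b2 and Hbb-bt fell too, near-identical copies among which reads cannot be placed with certainty. These 5 haemoglobin rows were the called members of 16 erythroid genes (7 lower and 1 higher adjusted over the list alone, median -0.30, adjusted p = 0.238 with an estimated correlation), none of them called with a robust fit. On leaving out libraries, Hbb-b1 and Hbb-bs had nearly the same fold changes (-2.504 to -1.881 and -2.483 to -1.869). So did Hbb-b2 and Hbb-bt (-1.809 to -1.533 and -1.787 to -1.522). These pairs may hold largely the same reads, so the 5 rows are not separate observations. Apol7c, from 18.7 ± 3.41 to 4.82 ± 1.35 CPM, and Erdr1, from 85 ± 26.4 to 32 ± 15.9, completed the list of 8 largest falls with Ahnak. Platelet and megakaryocyte genes rose in 9 of 12 cases (10 adjusted over the list alone, median 1.80, adjusted p = 0.0419 with an estimated correlation). The platelet chemokine gene Pf4 went from 9.35 ± 1.35 to 43.4 ± 11.1 CPM and Ppbp from 11.8 ± 4.22 to 55.7 ± 14.8. Of 8 tested NK-cell genes (17 listed), Gzma (0.133 ± 0.23 and 7.16 ± 2.87 CPM) and Il2rb (1.12 ± 0.265 and 4.36 ± 0.656) rose, 6 adjusted over the list alone. The list had adjusted p = 0.0419 with an estimated correlation. Gzma, near 0 in control, could pass the filter only through groups where it was higher. The NK-cell p-values here and below may therefore lean towards a rise. Of 6 tested neutrophil genes (22 listed), 3 rose (4 adjusted over the list alone, median 1.53, adjusted p = 0.277 with an estimated correlation), such as S100a9, from 2.88 ± 0.784 to 24.4 ± 20.7 CPM. Of 27 monocyte and macrophage genes, 6 rose (7 adjusted over the list alone, median 0.48, adjusted p = 0.353 with an estimated correlation), among them C1qb, from 2.34 ± 0.921 to 7.16 ± 3.07 CPM (not called without control replicate 2). For monocytes and macrophages the count was 2 without control replicate 1, 1 without control replicate 2 and 3 without ODN replicate 2.

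**Figure D1:**
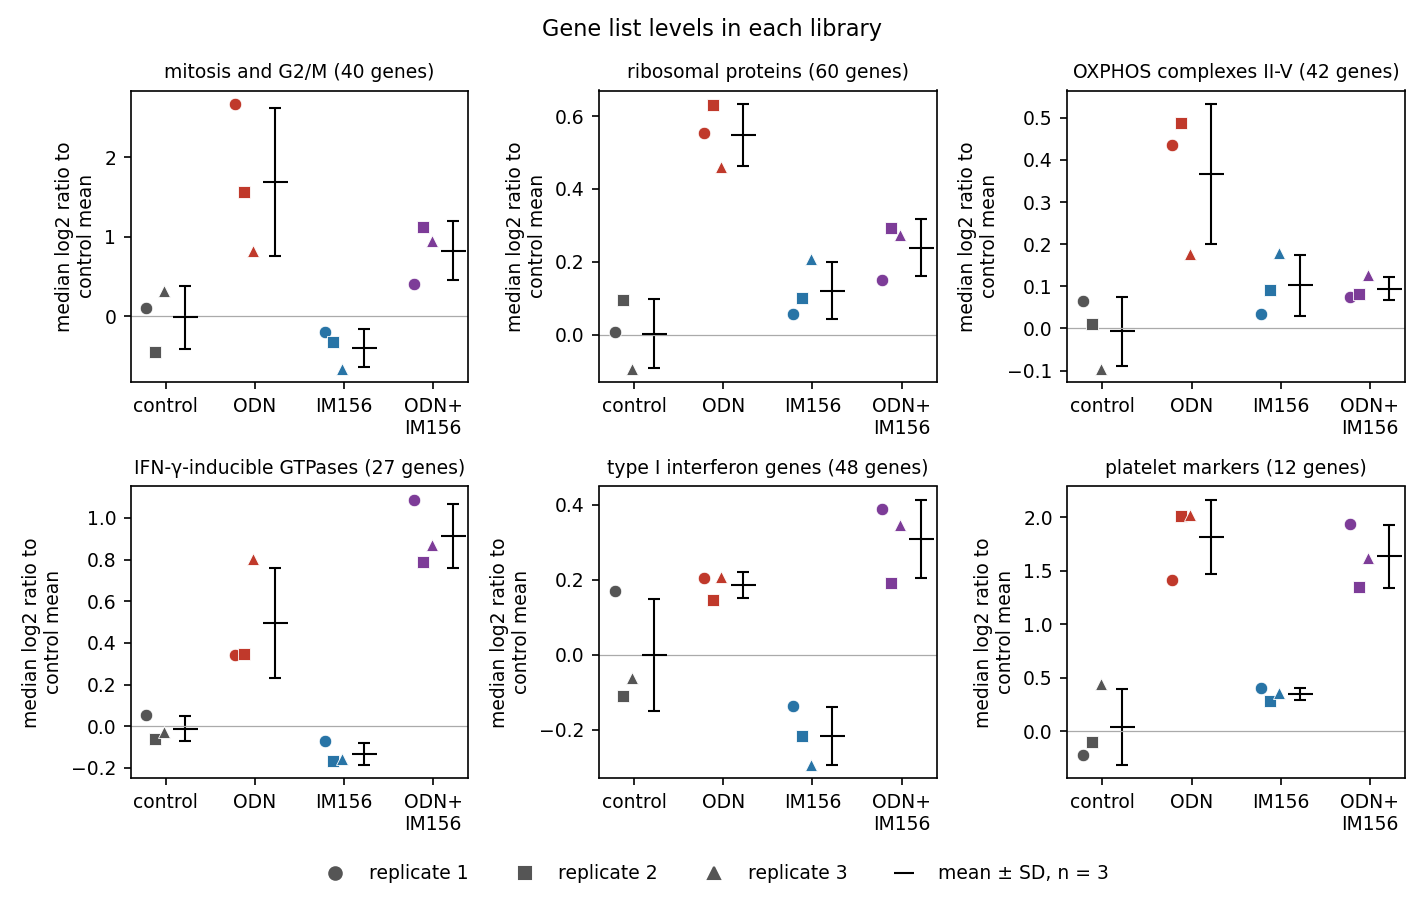
Median log2 level of 6 gene lists in each of the 12 libraries, relative to the mean of the control libraries (vertical axis, log2; horizontal axis, treatment group). Points are libraries and bars are means of 3; in the ODN group the mitosis genes lie at 2.67, 1.56 and 0.82 and the ribosomal protein genes at 0.55, 0.63 and 0.46.

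IM156 against control asks what the inhibitor and its injections did without ODN. No single gene changed by a called amount: edgeR called 0 of 11857 genes, DESeq2 called 2, and 439 genes (3.7%) had an unadjusted p below 0.05. The 5 genes of smallest p, none of which passed, were Eps8l1 (40.3 ± 5.14 CPM in control and 19.4 ± 1.51 with IM156, log2 fold change -1.05, SE 0.213, adjusted p = 0.631), Chst11 (4.34 ± 1.25 and 14.4 ± 6.42), Cacnb4 (6.87 ± 1.34 and 25.1 ± 20.5), Capn11 and Sla (154 ± 16.3 and 200 ± 7.5). Capn11 had 50 counts over the control libraries and 0 over the IM156 libraries, which is at least 17.2-fold lower against a floor of 3 counts over the group. No respiratory chain gene was called. Uqcrh was at 438 ± 41 CPM in control and 496 ± 47.4 with IM156, and Ndufa5 at 86.6 ± 3.98 and 107 ± 3.03. The stress genes Ddit3 (62.6 ± 7.99 and 61.5 ± 4.06) and Asns (1.23 ± 0.632 and 1.1 ± 0.46) were not called, nor were Cd69, Cd86, Isg15, Mki67 and Prdm1.

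Small shifts shared by whole lists passed camera only at the preset correlation (12 of 34 lists, 6 in each direction; 0 with an estimated correlation and 0 with fry). The type I interferon-stimulated genes had a median of -0.22 with 44 of 48 members negative (adjusted p = 0.236 with an estimated correlation), such as Usp18 at 18.3 ± 1.28 CPM in control and 12 ± 1.28 with IM156. The interferon-gamma inducible list had a median of -0.12 (adjusted p = 0.746 with an estimated correlation), the mitosis genes -0.45 (0.746), germinal centre genes -0.54 (0.288), erythroid genes -0.99 (0.0538) and neutrophil genes -0.71 (0.746). IM156 replicate 3 stood apart in the erythroid genes, with Hba-a1 at 45.55 CPM against 265.7 and 217.7 in replicates 1 and 2, and without it the list median was -0.57. Medians were positive for ribosomal protein genes (0.13, adjusted p = 0.746 with an estimated correlation), complex I (0.09, 0.789), complexes II to V (0.09, 0.746), immediate-early genes (0.17, 0.236), monocyte genes (0.16, 0.789) and platelet genes (0.25, 0.746). Over all 34 lists, no member was called over all genes tested.

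ODN+IM156 against ODN asks what the inhibitor and its injections changed in the presence of ODN, the contrast closest to the series title. The largest change was in Slc15a2, which encodes the peptide transporter PEPT2 and lies on chromosome 16 at 36750177 to 36784962. It fell from 27.9 ± 7.11 to 2.86 ± 1.8 CPM (log2 fold change -3.24, SE 0.372, adjusted p = 0.000519) and was called without each library in turn. Sdhd, the membrane anchor subunit of complex II, fell from 81.3 ± 10.8 to 52.4 ± 5.69 CPM (-0.64, SE 0.114, adjusted p = 0.0349), a level like that of control (52.5 ± 3.2). The transcription factor genes Fosb, from 77.2 ± 17.1 to 172 ± 44.3 CPM (1.16, SE 0.182, adjusted p = 0.017), and Klf4, from 66.9 ± 12.7 to 132 ± 25.2 (0.98, SE 0.148, adjusted p = 0.0133), rose to about their control levels of 151 ± 25.3 and 146 ± 25.8. Armc9 (15.4 ± 2.87 to 27.9 ± 2.84 CPM), the forkhead factor gene Foxo4 (58.3 ± 4.27 to 88.6 ± 5.28), Phxr4 (31.2 ± 4.19 to 57.6 ± 6.57) and 1 clone-named transcript rose too. Phxr4 lies inside Maml2 on the same strand, so the source of its reads is uncertain. In all edgeR called 8 genes, 6 higher and 2 lower, and 1919 genes had an unadjusted p below 0.05. More genes were lower than higher with DESeq2, which called 373 (143 higher, 230 lower), a robust fit, 124 (42 and 82), and no filter, 664 (219 and 445). With a strict filter, library totals alone or the length correction, most of the 10, 11 and 9 called genes were higher. The count was 1 without ODN+IM156 replicate 1 or 3, 2 without ODN replicate 2, 5 without ODN+IM156 replicate 2 and 794 without ODN replicate 3 (267 higher, 527 lower). Klf4, Fosb and Sdhd lost their calls without ODN replicate 2, ODN+IM156 replicate 1 or ODN+IM156 replicate 3, and Armc9, Foxo4 and Phxr4 without any library but ODN replicate 3.

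Many genes raised by ODN had lower levels when IM156 was added, without passing as single genes. The same ODN libraries served in both comparisons, which alone favours a fall of genes that were high in them. Of 10 splits of the libraries compared here, the real one included, 5 called at least as many lists. For 60 of 60 ribosomal protein genes the fold change was negative (median -0.32), 0 called over all genes tested by edgeR, 38 by DESeq2 and 53 lower adjusted over the list alone. As a list they passed camera at the preset correlation and had adjusted p = 0.395 with an estimated correlation. Rps12, the member with the smallest p, was at 782 ± 83.7 CPM in ODN and 571 ± 31 in ODN+IM156 (adjusted p = 0.0619). The 40 mitosis genes were all negative as well (median -1.01, 37 lower adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). Cdk1 was at 75.7 ± 41.3 and 33.2 ± 8.48 CPM and Mki67 at 196 ± 136 and 92.4 ± 28.8. Without ODN replicate 1 the median of the mitosis genes was -0.36, and without ODN replicate 3 it was -1.32 with 38 called lower. The S-phase genes had a median of -0.48 (adjusted p = 0.448 with an estimated correlation) and did not pass camera without ODN replicate 1. Complexes II to V had a median of -0.28, with Sdhd called and 23 lower adjusted over the list alone (adjusted p = 0.398 with an estimated correlation), and complex I a median of -0.23, with 11 lower adjusted over the list alone (0.448). Going the other way, the interferon-gamma inducible list had a median of 0.47, with 0 called by edgeR, 9 by DESeq2 and 12 higher adjusted over the list alone (adjusted p = 0.395 with an estimated correlation). Nlrc5, the activator of MHC class I genes, was at 65.6 ± 13.7 and 95 ± 11.3 CPM. Of 21 immediate-early genes, Klf4 and Fosb were called and 7 adjusted over the list alone (median 0.10, adjusted p = 0.395 with an estimated correlation). The other lists past camera at the preset correlation were TCA cycle, endoplasmic reticulum, neutrophil and erythroid genes (medians -0.14, -0.10, -1.03 and -0.44), and type I interferon-stimulated and mTORC1 and MYC-linked genes (medians 0.11 and 0.12). Their adjusted p with an estimated correlation was 0.448 for all but the endoplasmic reticulum (0.593) and interferon (0.672) lists. Cd86, Cd69, Isg15, Prdm1, Ddit3 and Asns were not called.

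**Figure D2:**
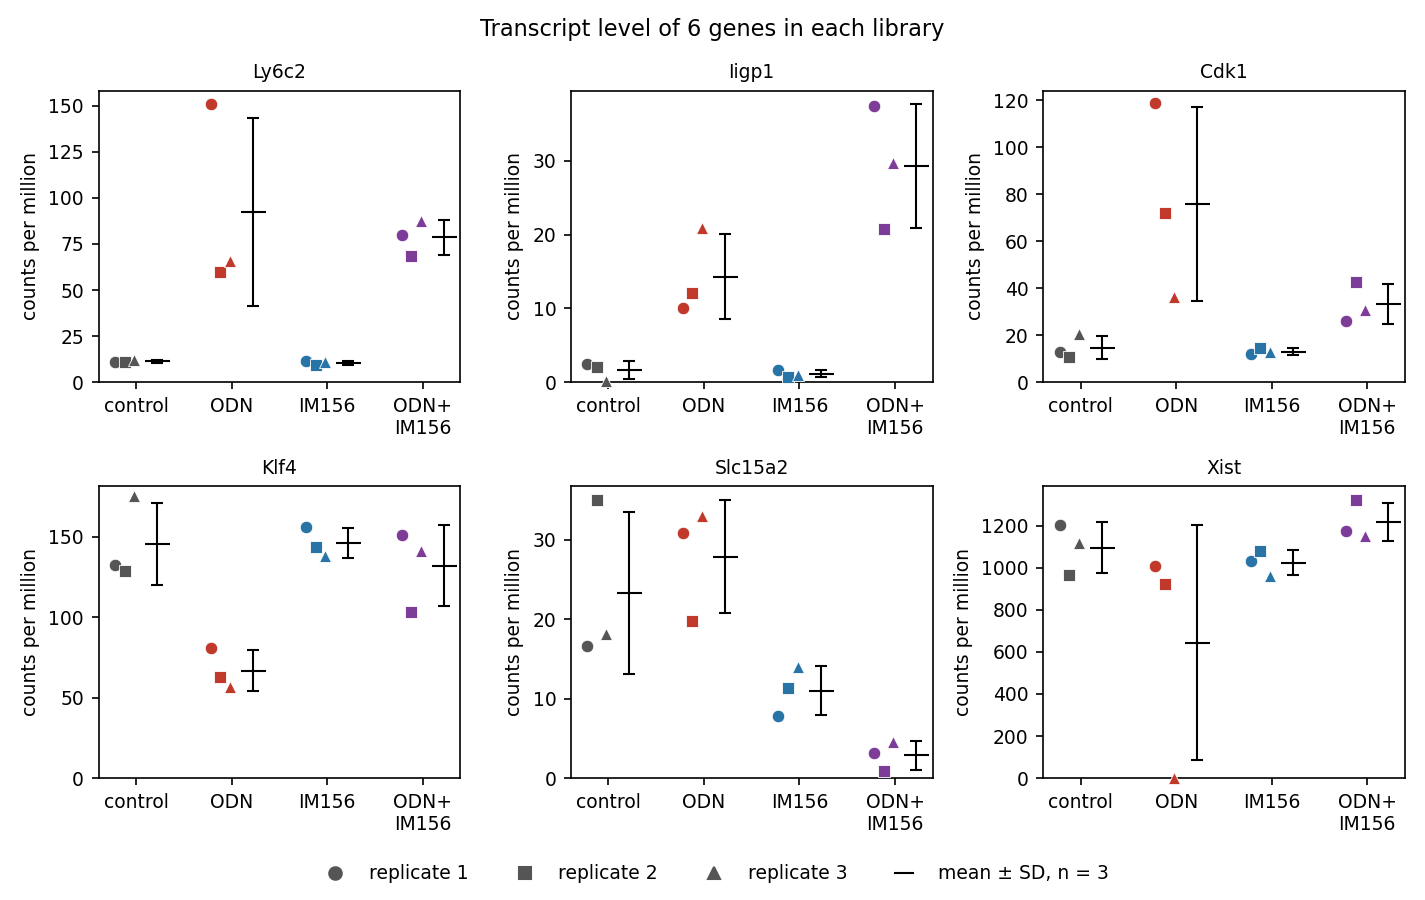
Level of Ly6c2, Iigp1, Cdk1, Klf4, Slc15a2 and Xist in CPM in each of the 12 libraries (vertical axis, CPM from 0, horizontal axis, treatment group), with points for libraries and bars for the mean of 3. Slc15a2 lies at 0.951 to 4.52 in ODN+IM156 and at 19.7 to 33 in ODN.

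ODN+IM156 against control gives the response to both compounds and their injections together. Of 27 interferon-gamma inducible genes, 16 rose (24 adjusted over the list alone, median 0.93, adjusted p = 0.00734 with an estimated correlation). Iigp1 went from 1.59 ± 1.22 to 29.3 ± 8.38 CPM (log2 fold change 4.19, SE 0.427, adjusted p = 9.78e-06), Gbp2 from 25.9 ± 1.07 to 72.4 ± 6.71 and Gbp6 from 5.05 ± 0.357 to 22.8 ± 4.26. Serpina3f, from 8.77 ± 0.599 to 64.2 ± 12.1 CPM, Ly6c2, Tgtp1, Tgtp2, Ppbp and Cadm1 rose too. Slc15a2 (23.3 ± 10.2 to 2.86 ± 1.8 CPM), Apol7c, Ahnak and 5 haemoglobin rows, some of which may share reads as above, fell. Cadm1 was not called without control replicate 1, control replicate 2, ODN+IM156 replicate 1 or ODN+IM156 replicate 3. In all 188 genes were called, 148 higher and 40 lower (324 by DESeq2; 1529 with an unadjusted p below 0.05). Of type I interferon-stimulated genes 8 of 48 rose (18 adjusted over the list alone, median 0.28, adjusted p = 0.0861 with an estimated correlation), led by Ly6a, Ifi44 and Zbp1. The count was 4 without control replicate 2 and 5 without control replicate 3, ODN+IM156 replicate 1 or ODN+IM156 replicate 3. Mitosis genes were not called here, with 0 of 40 called by edgeR and by DESeq2 and 17 higher adjusted over the list alone (median 0.86, adjusted p = 0.359 with an estimated correlation). Mki67 was at 48.1 ± 19.2 and 92.4 ± 28.8 CPM (adjusted p = 0.262). Of 38 S-phase genes, Pole and Mcm10 rose (7 adjusted over the list alone, median 0.44, adjusted p = 0.393 with an estimated correlation), and neither was called without control replicate 2 or ODN+IM156 replicate 3. Of ribosomal protein genes Rplp0 rose, a call lost without control replicate 2, control replicate 3, ODN+IM156 replicate 2 or ODN+IM156 replicate 3, with 31 adjusted over the list alone (median 0.23, adjusted p = 0.23 with an estimated correlation). Among other cell types, 8 of 12 platelet genes rose (5 without control replicate 2, adjusted p = 0.0151 with an estimated correlation) and 5 of 16 erythroid genes fell (median -0.74, adjusted p = 0.0221 with an estimated correlation), none with a robust fit. Gzma of 8 NK-cell genes rose (0.0218), but was not called without control replicate 2 or 3. Of 19 dendritic cell genes, whose cell of origin was not tested, Xcr1, Clec9a, Itgax and Irf8 rose (0.124). Of these, 2 were called without ODN+IM156 replicate 1, and Clec9a only without ODN+IM156 replicate 2. Monocyte and macrophage markers summed to 438 ± 38.2 CPM in control and 575 ± 40.4 in ODN+IM156. The whole count of 188 was 88 without control replicate 2, 111 without ODN+IM156 replicate 1 and 96 without ODN+IM156 replicate 3.

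ODN+IM156 against IM156 gives the response to ODN and its injections in animals treated with IM156. Of the same list, 19 of 27 interferon-gamma inducible genes rose (26 adjusted over the list alone, median 1.22, adjusted p = 0.00373 with an estimated correlation). Iigp1 went from 1.16 ± 0.487 to 29.3 ± 8.38 CPM (4.67, SE 0.446, adjusted p = 3.12e-06) and Tgtp1 from 9.97 ± 0.746 to 55.7 ± 9.61. Of type I interferon-stimulated genes 19 of 48 rose (37 adjusted over the list alone, median 0.59, adjusted p = 0.0218 with an estimated correlation), 11 without IM156 replicate 2 and 12 without IM156 replicate 3 or ODN+IM156 replicate 3. Of mitosis genes 21 of 40 rose (35 adjusted over the list alone, median 1.34, adjusted p = 0.195 with an estimated correlation), Top2a from 70.1 ± 17.7 to 218 ± 54 CPM. Of the list mitosis and G2/M phase, 0 were called without IM156 replicate 3, ODN+IM156 replicate 2 or ODN+IM156 replicate 3, 2 without IM156 replicate 2 and 4 without IM156 replicate 1. Among other cell types, 6 of 12 platelet genes rose (9 adjusted over the list alone, median 1.29, adjusted p = 0.0338 with an estimated correlation), Ppbp from 17 ± 2.5 to 50.6 ± 7.83 CPM and Pf4 from 12.8 ± 3.56 to 31.7 ± 4.69. Of 8 NK-cell genes, Gzma, Nkg7 and Il2rb rose (median 1.71, adjusted p = 0.0338 with an estimated correlation), with 0 or 1 called without any 1 library. S100a8 of the neutrophil genes (1.77 ± 1.05 to 9.55 ± 1.52 CPM) and the dendritic cell gene Xcr1 (4.38 ± 0.767 to 19 ± 10.5) rose as well, S100a8 not without IM156 replicate 1 or 2. Hba-a1 (176 ± 116 to 46.4 ± 20.1 CPM), Hbb-b1 and Hbb-bs fell, calls that held only without IM156 replicate 3. Where the libraries of both groups did not overlap, the largest falls, beside Slc15a2, Apol7c and Ahnak, were in genes such as Zfp36l2, an mRNA decay factor (505 ± 23.7 to 183 ± 50.9 CPM, -1.46, SE 0.263, adjusted p = 0.00329), Tsc22d3, a glucocorticoid-induced gene (782 ± 88.6 to 353 ± 49.4), and the chemokine receptor gene Cxcr4 (410 ± 48.4 to 200 ± 31.3). Cxcr4 was not called without any 1 of the 6 libraries, and Slc15a2 was not called without IM156 replicate 3. In all edgeR called 293 genes, 206 higher and 87 lower (438 by DESeq2; 1706 with an unadjusted p below 0.05). The count was 153, 114 and 121 without IM156 replicates 1, 2 and 3, and 174, 142 and 117 without ODN+IM156 replicates 1, 2 and 3. A fit of only these 2 groups called 892 genes (590 higher, 302 lower). That is more than the 598 for ODN against control in such a fit, the reverse of the order with all 12 libraries (1255 for ODN against control). The 2 numbers of calls therefore do not rank the ODN responses with and without IM156.

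Whether IM156 altered the ODN response was tested as an interaction. edgeR called 0 genes, DESeq2 called 165, and 1453 genes had an unadjusted p below 0.05. The genes of smallest p were Armc9 (log2 difference 1.24, SE 0.211, adjusted p = 0.131), Capn11, Rpl30 (-0.62, SE 0.127, adjusted p = 0.154), the noncoding RNA Snhg8 (-0.60) and Klf4 (0.98). Without ODN replicate 3 the count was 260, and without ODN replicate 1 it was 2. At the preset correlation 11 of 34 lists passed camera, with 0 passing at an estimated correlation and 0 with fry. The ribosomal protein genes were all negative in the interaction (median -0.46, adjusted p = 0.327 with an estimated correlation) and 26 of 27 interferon-gamma inducible genes were positive (median 0.63, 0.327).

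Across the 1255 genes called for ODN against control, the ODN response with IM156 had a slope of 0.518 on the response without it (0.415 without ODN replicate 3 to 0.563 without IM156 replicate 1). Genes are not independent replicates, so no p is given. In counts simulated with the same response in both, the slope was 0.752 (0.708 to 0.796 over 20 simulations) with shrunk effects. With effects as fitted it was 0.808 (0.788 to 0.828). The simulations hold no correlation between genes and give all groups the same spread for a gene. The real ODN libraries differed most among themselves. Wider spread in ODN by itself lowers this slope and favours opposite signs. Distance from the simulated values, here and below, therefore does not by itself show a smaller response. When genes were picked instead by ODN+IM156 against IM156 (293 genes), the axes were swapped, so a smaller response with IM156 would raise the slope. This slope, of the response without IM156 on that with it, was 0.869, above the simulated 0.762 (0.724 to 0.81) and 0.823 (0.77 to 0.852). Over all 8232 genes of at least 10 CPM, picked by neither comparison, the slope with the first axes was 0.483. The simulated values were 0.774 (0.755 to 0.801) with shrunk effects and 0.851 (0.823 to 0.87) with effects as fitted. Of the 1255 genes, 92.7% had fold changes of opposite sign for ODN+IM156 against ODN, against 67.5% (65.2 to 70.2) in simulations with shrunk effects and 65.1% (62.7 to 67.1) with effects as fitted. Called in opposite directions were 6 genes, Sdhd up with ODN and down with IM156, and 5 the other way, against 0.342 by independent lists and means of 0.1 (shrunk effects) and 0.2 (effects as fitted) in the simulations. The number was 0 without ODN+IM156 replicate 1 or 3 and 650 without ODN replicate 3. Both comparisons share the 3 ODN libraries, which alone favours opposite signs.

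**Figure D3:**
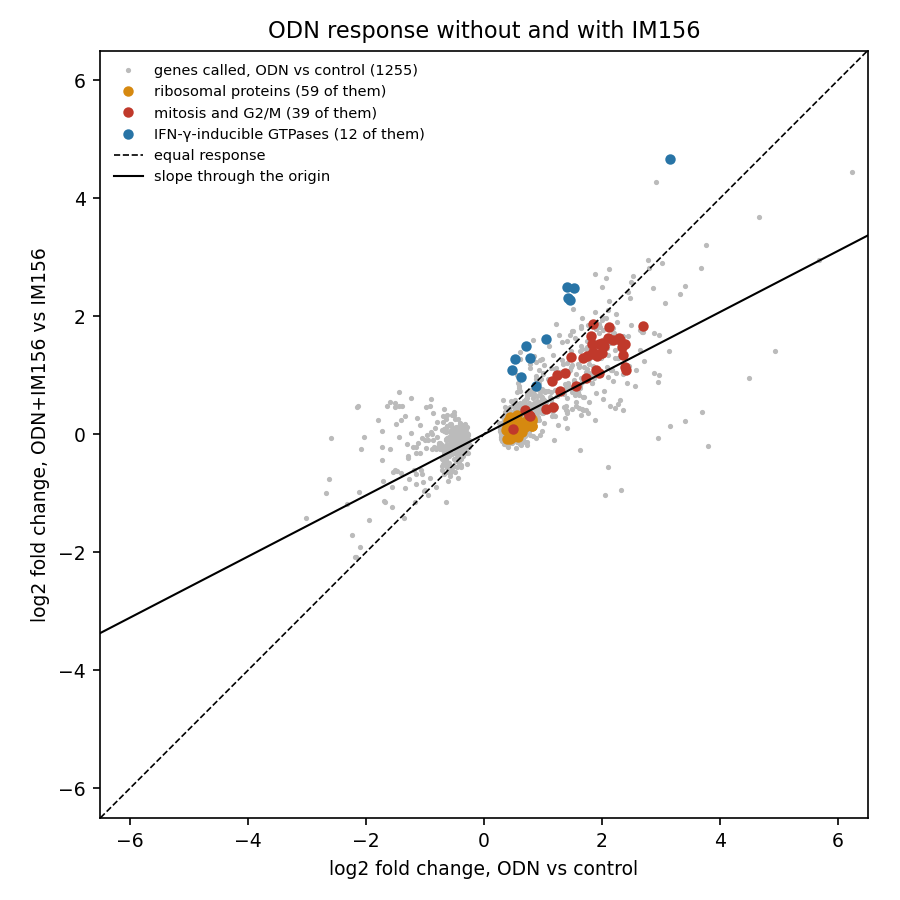
Log2 fold change of the ODN response without IM156 (horizontal axis, ODN against control) and with IM156 (vertical axis, ODN+IM156 against IM156) for the 1255 genes called for ODN against control; 2 points lie outside the axes. The fitted line through the origin has a slope of 0.518, below the line of equal responses.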

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

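The tests on transcript length, Rn45s, the X and Y chromosomes, sample exchange, erythroid cells and a single library were chosen only after the results were seen. The interaction asks whether the ODN response differed between animals with and without IM156, and 11 gene lists drew attention because camera at the preset correlation found such a difference. The median log2 differences were -0.292 for OXPHOS complex I subunits, -0.351 for complexes II to V, -0.191 for the TCA cycle, -0.456 for ribosomal protein genes, -0.363 for DNA replication and S phase, -0.505 for mitosis, -0.102 for the endoplasmic reticulum and -0.48 for platelet genes. They were 0.419 for type I interferon-stimulated genes, 0.628 for interferon-gamma inducible GTPases and 0.66 for germinal centre genes. None passed with an estimated correlation or with fry. The lists mitosis and G2/M phase and DNA replication and S phase did not pass without ODN replicate 1 (adjusted p = 0.707 and 0.939). Of 100 assignments of IM156 to the libraries, the real one included, 45 gave at least as many lists (highest other 16, real 11) and 12 gave a slope as low as the real 0.518 (lowest other 0.348), so values of this size also arise when IM156 is assigned at random. The same count for single genes carries no information, since the real number called was 0 and any assignment reaches it (100 of 100, highest other 6).

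The first pattern weighed is the rise of ribosomal protein and respiratory chain transcripts with ODN and their lower level when IM156 was added. A trend with transcript length as the whole cause does not account for the ribosomal protein genes, whose median after length correction was 0.438 with ODN and -0.248 for ODN+IM156 against ODN. For complex I the corrected median was 0.133 with 5 genes called, and a length trend cannot be told apart from a change in these genes. The low Rn45s share of ODN replicate 2 is not the cause either, since the lower ribosomal protein median of ODN replicates 1 and 3 was 0.46, above the highest control at 0.0947. The design offers the treatments themselves as the biological explanation, and the 3 libraries per group limit how far the ODN+IM156 part can be taken.

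The second pattern is ODN replicate 3, with 1 count of Xist and a profile nearer the ODN+IM156 libraries than ODN replicates 1 and 2. A male animal is argued against, as 0 counts fell on the Y-linked genes, although these genes had only 4 counts over all libraries. A single X chromosome fits: 4 of 6 genes known to escape X inactivation lay below all other libraries, such as Kdm6a at 51.8 CPM against 68 to 105. An exchanged ODN+IM156 sample is argued against by Slc15a2 at 33 CPM (0.951 to 4.52 in ODN+IM156) and by a ribosomal protein median of 0.46 (0.149 to 0.291). Its position of 0.815 between the ODN (0) and ODN+IM156 (1) means, however, lies inside the 0.576 to 0.968 of the ODN+IM156 libraries, so an exchange is not excluded.

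The third pattern is the rise of cell division transcripts with ODN. Erythroid precursors in the isolate are argued against, since the highest summed erythroid level of an ODN library was 323 CPM and the lowest of a control 748.25 CPM. Haemoglobin transcripts made up most of that sum in control, so a rise of precursors low in haemoglobin could be hidden. Granulocyte precursor transcripts rose by 0.267 CPM in sum, against 386 CPM for Top2a. The single library ODN replicate 1 is not the whole cause, as 34 mitosis genes were called without it. Division of the B cells themselves is a biological explanation the design gives, and it was not separated from a change in which B cells were recovered. Nor was it separated from dividing cells of types other than erythroid and granulocyte precursors, which were not tested. Summed markers rose with ODN for NK cells (31.4 to 56.4 CPM), monocytes (438 to 563), neutrophils (25.2 to 85.1), platelets (93.4 to 283) and dendritic cells (1922 to 2243). The dendritic cell list was already high in control, and which cells its transcripts came from was not tested. T-cell and stromal markers hardly moved.

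Each comparison of 3 against 3 libraries can be split in 10 ways, the real one included, too few for a share under 0.05. Splits with as many genes called as the real one numbered 1 for ODN against control (real 1255, highest other 2), 10 for IM156 against control (0 and 0, reached by any split), 2 for ODN+IM156 against ODN (8 and 32), 1 for ODN+IM156 against control (188 and 0) and 1 for ODN+IM156 against IM156 (293 and 0). For gene lists the numbers were 1 (20 and 17), 3 (12 and 12), 5 (13 and 14), 1 (17 and 14) and 1 (13 and 12), in the same order. The overlap of opposite calls was reached in 2 splits (6 and 26). The split with 32 genes exchanges ODN replicate 3 with ODN+IM156 replicate 2 and calls several times the real count, while the other 8 called 0. The cause of this split was not tested.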

How the results depend on the processing

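Of 239 called results of named genes, 121 kept direction and call under every alternative but the 2-fold minimum and 0 reversed; none of 86 list calls changed direction with another scaling. Leaving out 1 library gave 763 to 1874 genes for ODN against control, 0 to 1 for IM156 against control, 1 to 794 for ODN+IM156 against ODN, 88 to 180 against control, 114 to 174 against IM156 and 0 to 260 for the interaction. Gene lists ranged over 17 to 23, 10 to 12, 9 to 14, 14 to 18, 12 to 14 and 8 to 12 in that order, the slope over 0.415 to 0.563 and the opposite calls over 0 to 650. With the replicate number as a block, ODN+IM156 against ODN had 3 genes (13 with length correction) and the opposite calls were 2; no other count moved by over 1.5 times. The numbers do not pair the libraries: 3 of 18 same-numbered pairs correlated above 0.1 (-0.165 to 0.115), and 3 of 12 libraries were closest to their own number. Without a filter the counts were 53 for IM156 against control, 664, 531 and 652 for ODN+IM156 against ODN, control and IM156, and 276 for the interaction. DESeq2 gave 2, 373, 324 and 165 for IM156 against control, ODN+IM156 against ODN, ODN+IM156 against control and the interaction; the robust fit gave 124 for ODN+IM156 against ODN. Fits of only the groups compared gave 598, 6, 1, 396 and 892 for the 5 comparisons. The 2-fold minimum left 351, 2, 95 and 151, fewer by construction. Lists at an estimated correlation numbered 2, 0, 0, 4, 4 and 0, and with fry 0 for IM156 against control, ODN+IM156 against ODN and the interaction and 7 for ODN+IM156 against IM156. The slope was 0.602 with the strict filter and 0.483 over all genes of at least 10 CPM. The 0.869 with axes swapped is a different measure, the response without IM156 set on that with it. Apart from the 2-fold minimum and the swapped axes, the cause was not tested. Spread between libraries, not depth, limits well-counted genes; Tlr9, with 68 counts over all libraries, is limited by depth.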

Other observations

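Several named genes outside the groups above moved with ODN. Txn1, which encodes thioredoxin, rose from 141 to 250 CPM, and the serine synthesis genes Psat1 (23.5 to 37.5) and Psph (14.9 to 22.4) rose while Atf4, the transcription factor of the integrated stress response, fell from 502 to 393. Psat1 and Atf4 each lost the call on leaving out at least 1 library. The 18-gene ATF4 list did not pass camera (adjusted p = 0.937). Ifi30, a thiol reductase of antigen processing, rose from 462 to 711 CPM.

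A list of 16 pancreatic transcripts was chosen only after values were seen. They summed to 0.0993, 0.363 and 1.45 CPM in control, 0.833, 22.8 and 1.63 in ODN, 8.27, 21 and 42.9 in IM156 and 1.23, 0.739 and 8.32 in ODN+IM156, for replicates 1, 2 and 3 in order.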
